A study of Mus musculus with 4 samples.

How the data were processed

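Spatial gene expression was measured in 4 mouse tissue sections with 10x Visium, in a design of facial skin and oral mucosa, each unwounded and at postoperative day 4, with 1 section per group. Per the labels the mice were wildtype and the tissue was flash-frozen. The series also describes postoperative days 2 and 7 and single-cell and bulk RNA sequencing, which were not analysed here. Each section came as a matrix of UMI counts per gene and spot, deposited without normalization and made with Space Ranger 1.3.1 per the file headers. The submitters' processing notes name Space Ranger, Seurat and the mm10 genome. The aligner, annotation release and Seurat version are not given in the sources used here. Each matrix lists 32285 genes and holds only the spots flagged as under tissue, out of 4992 on an array. Spot positions were taken from the array coordinates, and tissue images were not used. No spot was dropped from the main values.

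UMIs were summed over all spots of a section for each gene and scaled to a common section total (CPM). Of the gene symbols, 78 were shared by more than 1 gene, and the first was used. Each CPM carries the exact 95% Poisson interval of its count, and each log2 ratio of CPM the exact conditional interval for a ratio of 2 Poisson counts. These intervals hold counting error only and say nothing about variation between animals. No test, p value or number of changed genes was computed from spots, which are not replicates. A ratio against a count of 0 is given as at least the fold against a floor of 3 UMIs, and a gene with 1 to 3 UMIs carries its interval.

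Genes were grouped by 35 fixed lists of cell type markers and pathway genes holding 391 genes, of which 389 matched a symbol and 2 did not. A list member was used in a comparison when it had at least 20 UMIs over both sections. It was counted as higher or lower when its CPM differed at least 1.5-fold and the Poisson intervals did not overlap. The list median used log2 ratios with 10 CPM added to both sides, and its interval came from 2000 resamples of the members with counts redrawn from Poisson distributions. The median was placed among those of 10000 random lists, in which each member was replaced by 1 of the 100 genes nearest in mean CPM. Where a member had no UMI in a section, putting it at the floor moved the median by at most 0.0582 log2 (24 of 140 medians had such a member). The all-gene median was taken over genes with at least 100 UMIs over both sections. The lists, thresholds, comparisons and most alternatives were fixed before the data were examined.

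Named genes followed a rule with 3 parts. The first names Gas6, Axl, Pros1, Mertk and Tyro3. The second allows 2 to 4 members of a list, largest absolute log2 ratio first, and many lists name 1 or none. The third names the 10 highest and 10 lowest genes with at least 100 UMIs whose direction was the same in all 16 pairs of section parts, leaving out mitochondrial, haemoglobin and predicted genes (Gm and Rik symbols). Each section was split into 4 parts at its median array row and column, and the same parts were left out 1 at a time as an alternative. Gene coordinates came from an NCBI annotation table of GRCm38.p6, and no genome sequence was used.

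Regions were found within each section by scaling spots to 10000 UMIs, log transformation, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5. They were named by their leading genes among the 10 highest ranked, with at least 20 UMIs. Region values are given for regions holding at least 1% of the section's UMIs, a limit set after seeing the data. Spearman's correlation across spots was computed between log-normalized Gas6 or Axl and each marker list's share of a spot's UMIs, and placed among the values of 200 genes with similar expression. Shares of spots with a UMI were also computed after thinning each spot to 1000 UMIs. Joint detection was compared with the product of the 2 genes' shares within classes of spot depth.

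Alternatives were TMM scaling, a total without mitochondrial genes and the 50 most abundant genes (103 genes in all), the mean over spots of spot CPM, spots with at least 1000 UMIs, spots with under 1% skeletal muscle markers, fibroblast-marker UMIs as reference, a pseudocount of 1 CPM, a minimum of 100 UMIs or none, resolution 1 and leaving out 1 part. The TMM factors were 1.24 in unwounded and 1.19 in day 4 facial skin and 0.732 in unwounded and 0.924 in day 4 oral mucosa. After seeing the data 6 more were added, among them the section labelled unwounded facial skin without its inflamed region and the day 4 oral section without its gland region. The lists of inflammatory cytokines, provisional matrix and muscle regeneration were followed as closely as those chosen earlier, also after seeing the data.

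The counting was tested on simulated data, in which section counts were drawn from Poisson distributions at the real totals and 50 genes were changed at each of 4 folds. At 4-fold either way 100% were recovered. At 2-fold, 100% and 92% of raised and lowered genes were recovered in facial skin and 92% and 90% in oral mucosa between day 4 and unwounded, and 94% to 100% between tissues. Of unchanged genes 0.0698%, 0.324%, 0.0898% and 0.221% were called in the facial wound, oral wound, unwounded tissue and day 4 tissue comparisons. Depth was 11939479 UMIs in the section labelled unwounded facial skin, 7285023 in unwounded oral mucosa, 9934290 in day 4 facial skin and 3004174 in day 4 oral mucosa, with 18396, 16838, 18239 and 16542 genes detected. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used, with edgeR 4.0.16 in R 4.3.3 for TMM.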

Results

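Gene expression was measured in 4 sections of flash-frozen tissue from wildtype mice with 10x Visium, in which a section lies on an array of barcoded spots and each captured transcript is counted through a unique molecular identifier (UMI). Facial skin and oral mucosa were each sampled unwounded and at postoperative day 4. Every group held 1 section, so there were no replicates, no test was run, and each statement below compares single sections. The 95% intervals of CPM and ratios are exact, for counting error only. Those of list medians come from resampling, and those of differences between ratios are approximate. A spot is a small region that can hold several cells of different types.

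The section labelled unwounded facial skin held 671 tissue spots and 11939479 UMIs, with a median of 16128 UMIs per spot. The unwounded oral section held 1288 spots and 7285023 UMIs. Its median was 98 UMIs per spot, since 652 of its spots held under 100 UMIs each and together 0.349% of its total, while its 523 spots with at least 1000 UMIs had a median of 13797. At day 4 the facial section held 1141 spots and 9934290 UMIs (median 5372 per spot) and the oral section 430 spots and 3004174 UMIs (median 5395.5). A count of 3 UMIs, the floor used for genes with no UMI, corresponded to 0.251 CPM (counts scaled to a common total per section) in unwounded facial skin, 0.412 in unwounded oral mucosa, 0.302 in day 4 facial skin and 0.999 in day 4 oral mucosa. Mitochondrial transcripts made up 2.71% and 2.75% of the UMIs in the unwounded and day 4 facial sections, against 20.8% and 11.9% in the oral ones. The 50 most abundant genes took 17.0% and 20.1% of the UMIs in the facial sections and 39.3% and 29.2% in the oral ones.

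Wounding went together with sex-linked transcripts in both tissues. The unwounded sections carried the Y-linked genes Ddx3y (49.2 CPM in facial skin and 38.4 in oral mucosa) and Eif2s3y (71.8 and 33.9), with 1 and 0 UMIs of Xist, the RNA that coats the inactive X chromosome. The day 4 sections held 909 and 84 Xist UMIs, no UMI of Ddx3y, Eif2s3y or Uty, and 5 and 1 of Kdm5d. Every wound comparison below is also between sections that differ in these genes.

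The series title names Gas6 and Axl in oral wound repair, and the first question was where this ligand and receptor stood in the 4 sections. Gas6 encodes a secreted vitamin K-dependent ligand of the TAM receptors, the tyrosine kinases Tyro3, Axl and Mertk, and Pros1 encodes protein S, a second ligand. In GRCm38.p6 coordinates Gas6 (ENSMUSG00000031451) lies on chromosome 8 from 13465374 to 13494535, Axl (ENSMUSG00000002602) on chromosome 7 from 25756500 to 25788924, Pros1 (ENSMUSG00000022912) on chromosome 16 from 62854307 to 62929346, Mertk (ENSMUSG00000014361) on chromosome 2 from 128698915 to 128803162 and Tyro3 (ENSMUSG00000027298) on chromosome 2 from 119797740 to 119818104. All 5 are protein-coding.

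Gas6 was higher in facial skin than in oral mucosa at both times. It stood at 178 CPM (170.1 to 185) in unwounded and 217 CPM (208 to 226) in day 4 facial skin, against 86.5 CPM (79.9 to 93.5) in unwounded and 75.6 CPM (66.1 to 86.1) in day 4 oral mucosa. Axl lay closer together, at 76.6 and 61.6 CPM in unwounded and day 4 facial skin and 78.7 and 74.6 CPM in oral mucosa. Facial skin therefore held 2.32 Gas6 UMIs per Axl UMI when unwounded (2.15 to 2.51) and 3.52 at day 4 (3.21 to 3.85), while oral mucosa held 1.10 (0.980 to 1.23) and 1.01 (0.839 to 1.22). The log2 difference of this ratio, oral minus facial, was -1.08 (-1.27 to -0.88) in the unwounded and -1.80 (-2.09 to -1.50) in the day 4 sections. Because both genes come from the same section, the ratio does not move with the scaling of section totals.

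**Figure D1:**
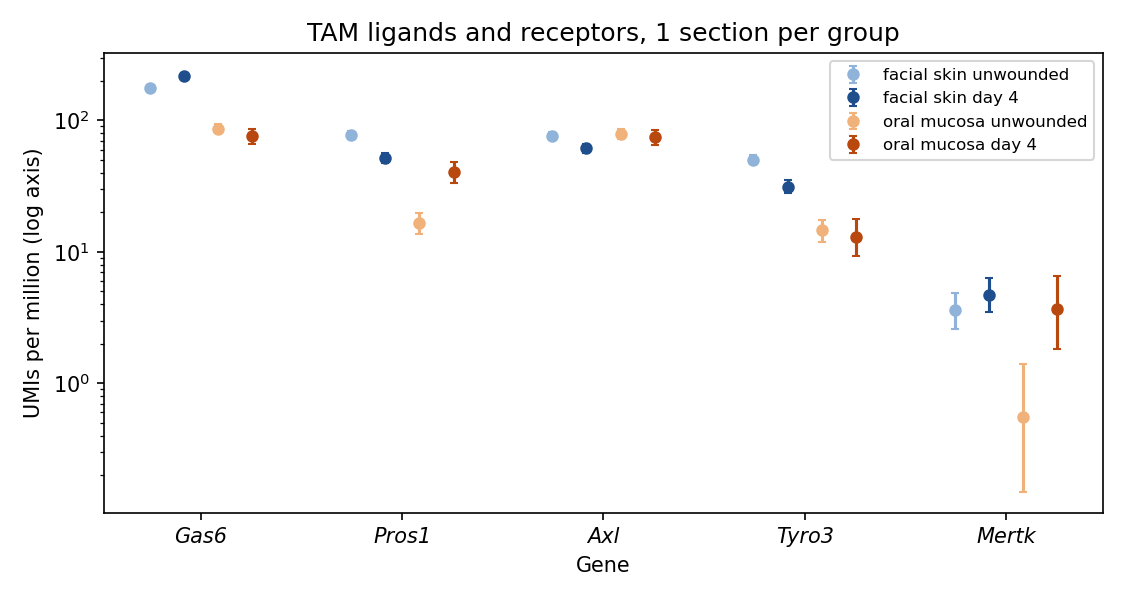
CPM of Gas6, Axl, Pros1, Tyro3 and Mertk (vertical axis, log scale) in the 4 sections, 1 per group, with exact 95% Poisson bars for counting error only. Gas6 is at 178 and 217 CPM in facial and 86.5 and 75.6 in oral sections. TMM keeps this order, but a fibroblast reference without Gsn does so only at day 4. Axl (61.6 to 78.7 CPM) spreads wider with TMM.

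Between the day 4 and unwounded sections of facial skin, the log2 ratio of Gas6 was 0.29 (0.20 to 0.37) and that of Axl -0.31 (-0.46 to -0.16). Leaving out part 2 of the unwounded facial section (each section was split at its median array row and column into 4 parts) took the Gas6 ratio to -0.02, and averaging over spots in place of summing gave 0.96 for Gas6 and 0.08 for Axl. Counted per fibroblast-marker UMI, the Gas6 ratio was -0.17. In oral mucosa the day 4 to unwounded ratios were -0.19 (-0.42 to 0.03) for Gas6 and -0.08 (-0.31 to 0.15) for Axl, neither of which was distinguishable from 0 at this depth. With the trimmed mean of M-values (TMM) as scaling these became -0.53 and -0.41. Averaging over spots took Axl to -0.75, and the ratios per fibroblast-marker UMI were -0.81 and -0.69. Pros1 was 1.51-fold lower in day 4 than in unwounded facial skin and 2.42-fold higher in day 4 than in unwounded oral mucosa, where 121 UMIs were counted in each section. Tyro3 was 1.61-fold lower at day 4 in facial skin, and its oral ratio was -0.16 (-0.73 to 0.38). Mertk had only 43, 47, 4 and 11 UMIs in unwounded and day 4 facial skin and unwounded and day 4 oral mucosa.

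Against facial skin, the log2 ratio of Gas6 in oral mucosa was -1.04 (-1.17 to -0.91) in the unwounded and -1.52 (-1.72 to -1.32) in the day 4 sections. Relative to the median of all genes, which was itself below 0 in both comparisons, the values were -0.44 and -1.16. The corresponding Axl ratios were 0.04 (-0.11 to 0.19) and 0.28 (0.05 to 0.50), or 0.64 and 0.64 relative to the median of all genes. Without part 2 of the day 4 oral section the day 4 Axl ratio was -0.05. Among spots with under 1% skeletal muscle markers the unwounded Axl ratio was -0.22, and per fibroblast-marker UMI the Gas6 ratios were -0.18 and -0.82 and the Axl ratios 0.89 and 0.98. Leaving out Gsn, a fibroblast marker that muscle also expresses, gave an unwounded Gas6 ratio of 0.82. Pros1 was 4.68-fold lower and Tyro3 3.45-fold lower in unwounded oral mucosa, and at day 4 Tyro3 was 2.41-fold lower while the Pros1 ratio was -0.35 (-0.65 to -0.06). Of the 5 members of this list, 0 were higher and 2 lower in day 4 against unwounded facial skin (median -0.27, percentile 4.73; 1 lower with TMM), 1 of 4 measured was higher and 0 lower in oral mucosa (median -0.08, relative -0.26, percentile 5.50), 4 of 5 were lower in unwounded oral mucosa than in facial skin (median -0.96, relative -0.36, percentile 14.4, TMM 1 and 3), and 2 of 5 were lower at day 4 (median -0.29, relative 0.07, percentile 52.6).

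For this and every other fixed list, a member counted as higher or lower when its CPM differed by at least 1.5-fold with non-overlapping intervals, and the rest are neither. The median is that of the members' log2 ratios with 10 CPM added, and example genes are named from the largest such ratio down. "Relative" is that median minus the median of all genes with at least 100 UMIs over both sections. The percentile places the median among 10000 random lists of the same size, matched on mean expression, as a description of these sections. Where TMM changed at least 2 of a list's calls, "TMM" gives its counts of higher and lower members. The all-gene median was -0.04 in day 4 against unwounded facial skin, 0.18 in day 4 against unwounded oral mucosa, -0.60 in unwounded oral mucosa against facial skin, and -0.36 at day 4. TMM moved the log2 section ratios by 0.06, -0.34, 0.76 and 0.36 and these medians to 0.01, -0.07, -0.11 and -0.10, so the last 3 comparisons carry the relative value.

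The wound comparison in oral mucosa asks how tissue at day 4 differed from unwounded tissue. The day 4 section was higher for neutrophil, macrophage, cytokine and matrix genes. All 10 measured neutrophil markers were higher (median 1.83, relative 1.66, percentile 100). S100a9 and S100a8, the calprotectin subunits that neutrophils carry, were 213-fold higher and 91.8-fold higher, and the gelatinase Mmp9 was 70.7-fold higher. Of the macrophage and monocyte markers 13 of 14 were higher and none lower (median 1.40, relative 1.23, percentile 100), led by lysozyme Lyz2 (5.38-fold higher), the protease cathepsin S, Ctss (6.59-fold higher), Ms4a7 (19.5-fold higher) and Adgre1, which encodes F4/80 (9.77-fold higher). Inflammatory cytokines and chemokines were higher for 12 of 13 (median 1.47, relative 1.29, percentile 100), among them the neutrophil attractants Cxcl5 (264-fold higher) and Cxcl3 (at least 276-fold higher, with 0 UMIs in the unwounded section) and the cytokine Il1b (134-fold higher). Without part 2 of the day 4 section the cytokine median was 0.63, and the neutrophil median was 2.48 without part 3 and 2.58 in spots with under 1% skeletal muscle markers. A pseudocount of 1 CPM gave 4.44 for neutrophil and 2.28 for macrophage markers.

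Matrix genes were also higher in the day 4 oral section. All 12 provisional matrix genes, those of early wound matrix, were higher (median 2.58, relative 2.41, percentile 100). Periostin, Postn, was 40.5-fold higher, osteopontin, Spp1, 128-fold higher, tenascin C, Tnc, 17.9-fold higher and the protease inhibitor Timp1 18.1-fold higher. Of the fibrillar collagen and matrix genes 15 of 16 were higher (median 1.60, relative 1.42, percentile 100, TMM 12 and 0), with Col1a1 6.88-fold higher and the collagen cross-linking enzyme Lox 16.5-fold higher. Matrix metalloproteinases and their inhibitors were higher for 6 of 9 and lower for none (median 0.75, relative 0.57, percentile 99.9), Mmp3 being 4.56-fold higher. Of 12 fibroblast markers, 6 were higher and 1 lower (median 0.67, relative 0.49, percentile 99.9, TMM 6 and 3), with Lum, the small proteoglycan lumican, 4.57-fold higher and Col3a1 3.94-fold higher. Among fibroblast lineage transcription factors 6 of 9 were higher (median 0.70, relative 0.52, percentile 99.95, TMM 5 and 1), first Runx1 (7.34-fold higher) and Twist1 (5.78-fold higher). Of 12 TGF beta pathway genes, 6 were higher and 0 lower (median 0.54, relative 0.37, percentile 99.6), with Tgfbi 2.51-fold higher and the receptor Tgfbr2 2.43-fold higher. Of 14 focal adhesion and YAP-TAZ genes, 6 were higher and 0 lower (median 0.44, relative 0.26, percentile 98.7), with the YAP target Ankrd1 21.1-fold higher and the integrin Itgb1 2.20-fold higher. Without part 2 of the day 4 section the provisional matrix median was 1.46 and the focal adhesion median -0.08, and without part 3 the provisional matrix median was 3.27.

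Over all oral spots, wound keratinocyte genes were higher for 11 of 13 and lower for none (median 1.10, relative 0.92, percentile 100, TMM 9 and 0). The cornified envelope gene Sprr2d was 35.2-fold higher and the stress keratin Krt17 16.7-fold higher. Basal keratinocyte markers went both ways (5 higher and 1 lower of 10; median 0.37, relative 0.19, percentile 93.0, TMM 3 and 2), Krt15 being 4.05-fold lower and Krt14 2.37-fold higher. Of 8 oral epithelium markers, 0 were higher and 2 lower (median -0.41, relative -0.59, percentile 0.29, TMM 0 and 4). Krt24 was 81.7-fold lower (log2 ratio -6.35, -8.63 to -4.80), while Krt13 and Krt4, the keratins of the layers above the basal one, were 1.48-fold and 1.47-fold lower and so not counted. Of 10 cornifying epidermis markers, 1 was higher and 1 lower (median -0.06, relative -0.24, percentile 16.6, TMM 1 and 3), with filaggrin, Flg, 21.1-fold higher and Krt10 3.84-fold lower. Of 12 proliferation genes, 4 were higher and 1 lower (median 0.29, relative 0.11, percentile 86.4, TMM 0 and 2), with Cdk1 1.82-fold higher. Without part 2 of the day 4 section the wound keratinocyte, basal keratinocyte, cornifying and proliferation medians were 0.18, -0.06, -1.46 and -0.23. Without part 3 the first 3 were 1.69, 1.01 and 0.58. Without part 3 of the unwounded section the cornifying median was 0.56 and the oral epithelium median 0.14. Without its part 4 the basal keratinocyte, oral epithelium and proliferation medians were -0.20, -1.12 and -0.14.

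Muscle and gland genes differed between the same oral sections. Genes of muscle regeneration were higher for 9 of 10 and lower for none (median 1.39, relative 1.21, percentile 100). Embryonic myosin, Myh3, was 61.7-fold higher, cardiac actin, Actc1, 5.33-fold higher, myogenin, Myog, 11.7-fold higher and the fusion factor Mymk 27.7-fold higher. Of 12 mature skeletal muscle markers, 0 were higher and 5 lower (median -0.36, relative -0.53, percentile 2.65, TMM 0 and 8), with the fast myosins Myh4 13.0-fold lower and Myh1 2.74-fold lower. Of 13 oxidative phosphorylation genes, 0 were higher and 0 lower (median -0.30, relative -0.48, percentile 1.51, TMM 0 and 8), with Sdha 1.44-fold lower. Salivary gland markers were higher for all 8 measured (median 3.76, relative 3.58, percentile 100), the mucin Muc5b being 216-fold higher and Dcpp1 127-fold higher. Erythrocyte genes were higher for all 5 (median 2.12, relative 1.94, percentile 99.97), Hba-a1 being 7.84-fold higher. Of 5 adipocyte markers, 0 were higher and 3 lower (median -1.11, relative -1.28, percentile 0), with Lpl, lipoprotein lipase, 2.81-fold lower and adipsin, Cfd, 50.9-fold lower (log2 ratio -5.67, -8.72 to -3.80). Leaving out parts of the sections moved several of these medians. Without part 2 of the day 4 section muscle regeneration was at 0.31, skeletal muscle at 0.32 and oxidative phosphorylation at 0.14. Without part 3 skeletal muscle was at -2.79, oxidative phosphorylation at -1.08, adipocyte at -1.97 and erythrocyte at 0.04. Without part 4 of the unwounded section skeletal muscle was at 0.23, adipocyte at -0.24 and oxidative phosphorylation at 0.01. In spots with under 1% muscle markers oxidative phosphorylation was at 0.09, and the salivary median was 1.59 without the gland region.

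Mast cell markers were higher for all 5 measured in the day 4 oral section (median 0.96, relative 0.78, percentile 99.97), the chymase Cma1 being 4.79-fold higher and the protease Cpa3 6.67-fold higher, and the median was -0.00 without part 3 of that section. Of 7 dendritic and Langerhans cell markers, 5 were higher and 0 lower (median 0.61, relative 0.43, percentile 99.7, TMM 2 and 0), led by the class II genes H2-Aa (2.18-fold higher) and H2-Eb1 (1.98-fold higher). Of 12 efferocytosis and scavenger genes, which serve the uptake of dead cells, 4 were higher and 1 lower (median 0.43, relative 0.25, percentile 97.7), with the lipid exporter Abca1 4.85-fold higher and Stab1 3.08-fold higher. Of 10 endothelial markers, 2 were higher and 0 lower (median 0.37, relative 0.20, percentile 95.4), with Cdh5 2.69-fold higher and Pecam1 1.43-fold higher. Of 10 pericyte and smooth muscle markers, 4 were higher and 0 lower (median 0.31, relative 0.14, percentile 83.8, TMM 1 and 1), with Acta2 2.17-fold higher and Tagln 1.64-fold higher. Of 6 Schwann cell markers, 0 were higher and 2 lower (median -0.33, relative -0.50, percentile 0.05). Of 2 T and NK cell markers, 1 was higher and 0 lower (median 0.35, relative 0.18, percentile 75.5). Of 13 hypoxia and glycolysis genes, 3 were higher and 3 lower (median -0.17, relative -0.35, percentile 0.235, TMM 1 and 6), with Hif1a 3.92-fold higher and the hexokinase Hk2 1.96-fold lower. Interferon response genes (0 higher and 1 lower of 13; median 0.01, relative -0.17, percentile 3.59) and sebaceous gland markers (1 higher and 0 lower of 6; median 0.04, relative -0.14, percentile 15.1, TMM 0 and 1) lay near 0 and turned to -0.16 and -0.22 with TMM. Of 8 oral and craniofacial transcription factors, 1 was higher and 1 lower (median -0.06, relative -0.24, percentile 2.45), with Msx1 2.92-fold higher and Pax9 1.60-fold lower. Of 3 hair follicle markers, 1 was higher and 1 lower (median -0.10, relative -0.27, percentile 8.30).

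The 10 highest genes in day 4 oral mucosa with 1 direction in all 16 pairs of parts were Muc5b, S100a9, Dcpp1, the platelet chemokine Ppbp (462-fold higher), Muc19, Gp2, Bpifb2, Wfdc18, Postn and Cxcl5. Parts 1 and 2 of the unwounded section held 18885 and 12574 UMIs, so pairs with them tested direction little. The 10 lowest were the metallothionein Mt3 (21.6-fold lower), Myh4, the chitinase-family gene Chil4 (10.1-fold lower), the lipoxygenase Alox15 (53.3-fold lower), Krt24, Serpinb3c, Lyg1, Lars2, Slurp2 and Ppp1r3c. Of 324 measured list genes, 157 were higher and 27 lower with CPM and 133 and 54 with TMM, or 85.3% and 71.1% higher among those counted.

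In facial skin the same question gave another set of differences. Neutrophil markers and inflammatory cytokines were lower in the day 4 section than in the section labelled unwounded, while adipocyte and cornifying epidermis genes were higher. All 11 measured neutrophil markers were lower (median -1.51, percentile 0). S100a8 stood at 3028 CPM in the section labelled unwounded and 74.4 at day 4 (40.7-fold lower), S100a9 at 2747 and 132, and the iron-binding Lcn2 was 22.0-fold lower. Inflammatory cytokines and chemokines were lower for 15 of 16 and higher for none (median -1.50, percentile 0), with Cxcl2 98.0-fold lower, Il1b 33.3-fold lower, Ccl3 30.9-fold lower and the prostaglandin synthase Ptgs2 9.84-fold lower. Wound keratinocyte genes were lower for 12 of 16 (median -0.86, percentile 0), among them the growth factor Hbegf (5.53-fold lower), Sprr1a (2.72-fold lower) and the urokinase receptor Plaur (3.86-fold lower).

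Macrophage, dendritic and T cell lists had medians below 0 in day 4 facial skin. Of 14 macrophage and monocyte markers, 0 were higher and 8 lower (median -0.42, percentile 0.01, TMM 0 and 6), led by the complement gene C1qc (1.80-fold lower) and Aif1 (1.99-fold lower), and averaging over spots gave a median of 0.18. Of 10 dendritic and Langerhans cell markers, 0 were higher and 7 lower (median -0.54, percentile 0.01), with H2-Ab1 1.99-fold lower and Cd209a 2.82-fold lower. Of 10 T and NK cell markers, 0 were higher and 6 lower (median -0.38, percentile 0). Of 13 efferocytosis and scavenger genes, 0 were higher and 3 lower (median -0.31, percentile 0.13, TMM 0 and 1, 0.05 averaged over spots), the haemoglobin scavenger receptor Cd163 being 6.44-fold lower. Mast cell markers went the other way (3 higher and 0 lower of 6; median 0.66, percentile 100, 1.39 averaged over spots), with Cma1 2.57-fold higher and Tpsb2 4.00-fold higher. Of 13 interferon response genes, 3 were higher and 2 lower (median 0.02, percentile 76.9), with Ifi27l2a 1.67-fold lower and Rsad2 2.04-fold higher.

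Fibrillar collagen and matrix genes were higher in day 4 facial skin for 6 of 16 and lower for none (median 0.35, percentile 99.99), first Col6a3 (2.61-fold higher) and Col1a1 (2.06-fold higher). Of 12 fibroblast markers, 4 were higher and 0 lower (median 0.40, percentile 99.99), with Col5a1 1.90-fold higher and the microfibril gene Mfap5 1.96-fold higher. Averaging over spots gave 1.06 for the collagen and 1.15 for the fibroblast median, and leaving out 1 part as little as 0.00127 and 0.0870. Of 11 fibroblast lineage transcription factors, 5 were higher and 0 lower (median 0.17, percentile 99.2), Prrx1 being 2.97-fold higher. The provisional matrix list was split, with 4 higher and 6 lower of 12 (median -0.48, percentile 0, 0.04 averaged over spots). Cthrc1, a secreted regulator of collagen deposition, was 13.8-fold higher, while the thrombospondin Thbs1 was 5.29-fold lower and Tnfaip6 4.59-fold lower. Of 11 matrix metalloproteinases and inhibitors, 1 was higher and 4 lower (median -0.50, percentile 0), with Mmp3 2.37-fold lower and Mmp12 3.94-fold lower. Of 12 TGF beta pathway genes, 1 was higher and 3 lower (median -0.20, percentile 1.76, 0.07 averaged over spots), with Ltbp1 2.13-fold lower. Of 14 focal adhesion and YAP-TAZ genes, 0 were higher and 2 lower (median -0.23, percentile 1.44), with Ccn1 3.27-fold lower.

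Skin appendage, fat and muscle genes also differed between the facial sections. Adipocyte markers were higher for 6 of 9 (median 0.84, percentile 100, 1.78 averaged over spots), led by the adipokine Adipoq (4.53-fold higher) and the fatty acid carrier Fabp4 (2.47-fold higher). Cornifying epidermis markers were higher for 9 of 12 (median 0.80, percentile 100), with Flg2 3.07-fold higher and Krt10 2.31-fold higher. Of 11 hair follicle markers, 6 were higher and 0 lower (median 0.29, percentile 99.98, 0.91 averaged over spots), with the inner root sheath keratin Krt27 3.23-fold higher. Erythrocyte genes were higher for all 5 (median 1.38, percentile 100), Hba-a1 being 6.11-fold higher. Muscle regeneration genes were higher for all 7 measured (median 0.57, percentile 100, 1.64 with a pseudocount of 1 CPM), Actc1 being 55.3-fold higher and Myh3 103-fold higher (log2 ratio 6.69, 4.17 to 12.01). Of 12 skeletal muscle markers, 1 was higher and 1 lower (median -0.21, percentile 2.60), with Myh1 1.70-fold lower and the calcium pump Atp2a1 1.55-fold higher. The skeletal muscle median depended on where muscle lay, at 1.91 without part 4 of the section labelled unwounded, -1.13 without part 3 of the day 4 section, 0.06 without its part 1 or its part 4, and 0.61 averaged over spots. Of 10 basal keratinocyte markers, 1 was higher and 0 lower (median -0.26, percentile 2.47), with Krt15 2.10-fold higher. Of 5 oral epithelium markers, scarce in skin, 0 were higher and 3 lower (median -0.21, percentile 1.36), with Krt84 6.66-fold lower.

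The other facial lists cover vessels, nerve, glands, metabolism, division and sex-linked genes. Endothelial markers (3 higher and 0 lower of 10; median -0.03, percentile 47.1), sebaceous gland markers (1 higher and 3 lower of 9; median -0.05, percentile 41.5) and oxidative phosphorylation genes (0 higher and 1 lower of 13; median -0.04, percentile 55) had medians near 0 that became 0.01, 0.02 and 0.02 with TMM. The sebaceous enzymes Awat1 and Elovl3 were 2.49-fold lower and 2.08-fold lower. Of 10 pericyte and smooth muscle markers, 3 were higher and 0 lower (median 0.24, percentile 99.9, -0.05 without part 2 of the section labelled unwounded), with Myl9 2.19-fold higher and Mylk 1.65-fold higher. Of 6 Schwann cell markers, 0 were higher and 1 lower (median -0.27, percentile 1.13, 0.05 averaged over spots). Of 14 hypoxia and glycolysis genes, 1 was higher and 1 lower (median -0.28, percentile 0.34), with Eno1 1.62-fold higher. Of 12 proliferation genes, 0 were higher and 0 lower (median 0.12, percentile 97.8). Of 6 oral and craniofacial transcription factors, 2 were higher and 0 lower (median 0.08, percentile 93.2), with Msx1 2.73-fold higher and Lhx6 3.31-fold higher. Only 2 salivary gland markers were measured, with Aqp5 4.13-fold higher and the peroxidase Lpo 2.64-fold lower (median 0.12, percentile 84.8). The sex-linked list, described above, was 1 higher and 4 lower of 5 in facial skin (median -1.46, percentile 0) and 1 higher and 4 lower of 5 in oral mucosa (median -0.79, relative -0.97, percentile 0).

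The 10 highest genes in day 4 facial skin with 1 direction in all 16 pairs of parts were Xist, the metallothionein Mt4 (12.7-fold higher), Cthrc1, the hair keratin-associated Krtap3-2 (14.2-fold higher), Actc1, Paqr7, Car6, the imprinted gene Nnat (32.3-fold higher), Wfdc21 and Sfrp4, a secreted Wnt antagonist (6.75-fold higher). The 10 lowest were S100a8, the acute-phase gene Saa3 (33.9-fold lower), Cxcl2, S100a9, Il1b, the defensin Defb8 (at least 333-fold lower), Lcn2, Eif2s3y, Atp12a and Clec4d (15.03-fold lower). Of 352 measured list genes, 72 were higher and 93 lower with CPM and 77 and 85 with TMM.

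Set side by side, the wound ratios of oral mucosa and facial skin went opposite ways by at least 1.5-fold in each tissue for neutrophil markers (1.83 and -1.51), inflammatory cytokines (1.47 and -1.50), wound keratinocyte genes (1.10 and -0.86) and adipocyte markers (-1.11 and 0.84), as list medians. Leaving out 1 part took the oral wound keratinocyte median to 0.18 and the adipocyte medians to -0.24 and 0.42. Provisional matrix genes (2.58 and -0.48), macrophage markers (1.40 and -0.42), metalloproteinases (0.75 and -0.50), dendritic and Langerhans cell markers (0.61 and -0.54) and efferocytosis genes (0.43 and -0.31) also had opposite signs, with under 1.5-fold in facial skin. Averaged over spots, the facial medians of provisional matrix, macrophage and efferocytosis genes were 0.04, 0.18 and 0.05. Collagen genes (1.60 and 0.35), muscle regeneration genes (1.39 and 0.57), mast cell markers (0.96 and 0.66), fibroblast markers (0.67 and 0.40) and erythrocyte genes (2.12 and 1.38) had positive medians in both tissues with CPM and with TMM, those of collagen and fibroblast genes in facial skin falling to 0.00127 and 0.0870 without 1 part. Without part 3 of the day 4 oral section the oral mast cell and erythrocyte medians were -0.00 and 0.04. Across 12474 genes with at least 100 UMIs over the 4 sections, Pearson's correlation of the oral and facial wound ratios was -0.0750 and Spearman's -0.00512, and 47.5% of genes had the same sign. This correlation is across genes, not replicates. No test of a difference between the tissues was possible with 1 section per group.

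**Figure D2:**
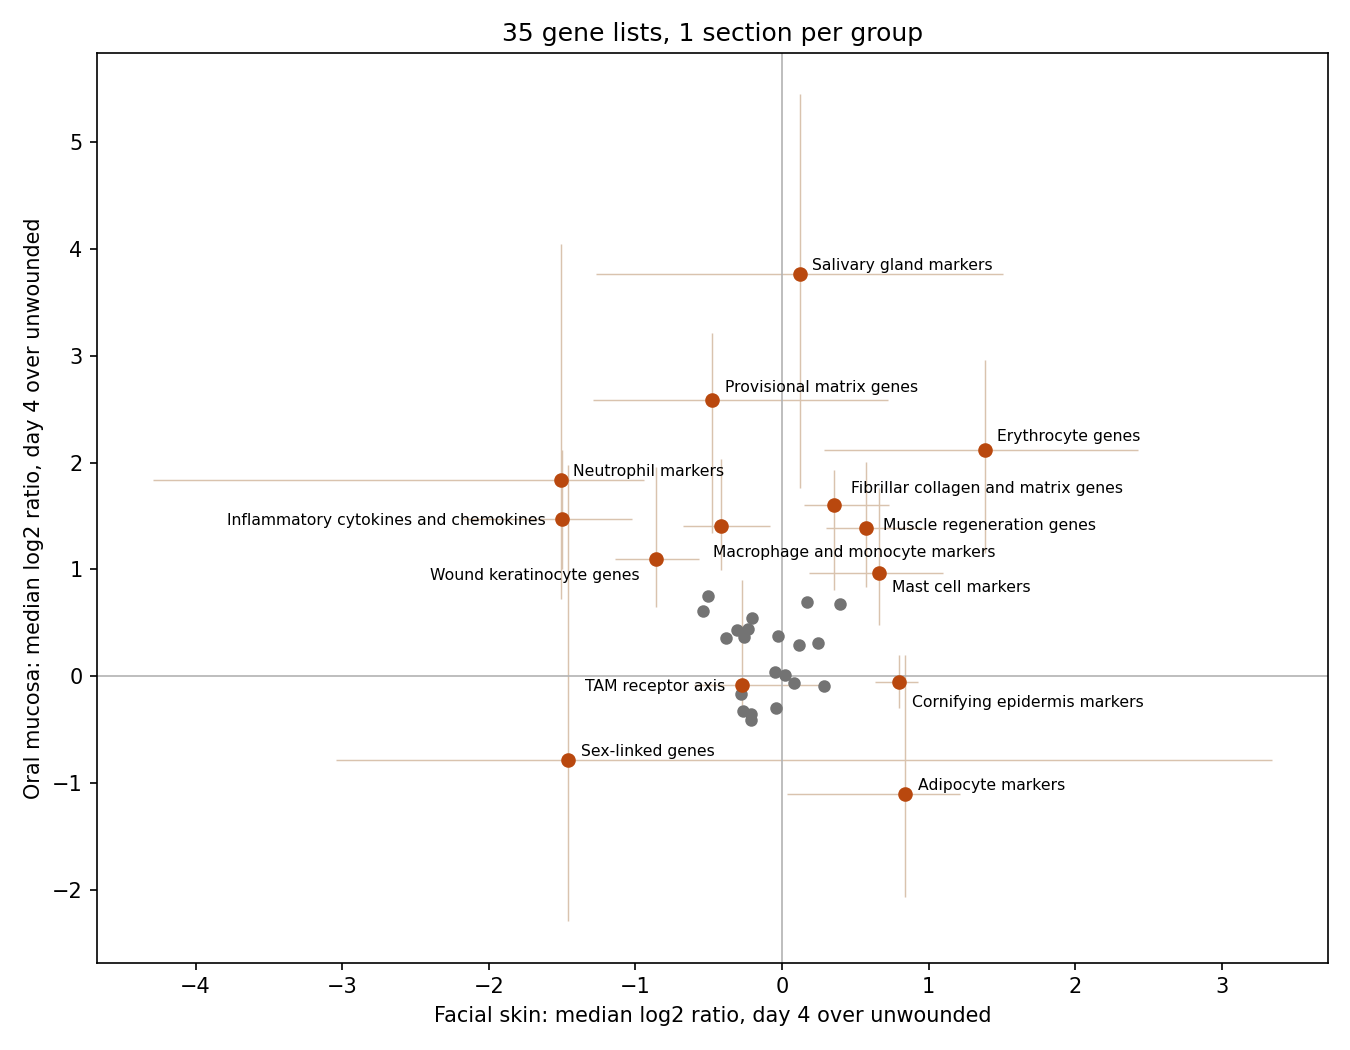
Median log2 ratio of each gene list, day 4 against unwounded, in facial skin (horizontal axis) and oral mucosa (vertical axis), 1 section per group. Bars are resampling intervals of the medians. Neutrophil markers (-1.51 in facial skin, 1.83 in oral mucosa) and inflammatory cytokines (-1.50, 1.47) have opposite signs, which TMM scaling does not turn.

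Unwounded sections compare tissues only if labels hold. Oral mucosa was higher for skeletal muscle, oral epithelium, oral transcription factor and oxidative phosphorylation genes, and facial skin for cornifying, hair, sebaceous, inflammatory and matrix genes. All 12 skeletal muscle markers were higher in oral mucosa (median 5.74, relative 6.35, percentile 100), with Myh2 144-fold higher, creatine kinase, Ckm, 96.6-fold higher and Tnni2 74.6-fold higher. Spots with under 1% skeletal muscle markers held 11749913 of the 11939479 facial UMIs and 1840017 of the 7285023 oral ones. Oral epithelium markers were higher for 7 of 8 (median 1.77, relative 2.37, percentile 99.97). Krt13 and Krt4 stood at 27097 and 14998 CPM in oral mucosa and at 2.26 and 1.26 in facial skin, and Sprr3 was 9131-fold higher (log2 ratio 13.16, 11.61 to 15.43). Of the oral and craniofacial transcription factors 7 of 8 were higher (median 1.55, relative 2.15, percentile 100), first the homeobox gene Pitx1 (86.2-fold higher). Oxidative phosphorylation genes were higher for 12 of 13 (median 1.26, relative 1.87, percentile 99.7), with the muscle isoform Cox6a2 115-fold higher, but the median was -0.09 in spots with under 1% muscle markers, where the skeletal muscle median was 3.58. Without part 3 of the oral section the oral epithelium median was 4.10, without its part 4 it was 2.55 and the transcription factor median 2.64, and without part 4 of the facial section the skeletal muscle median was 7.51.

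Epidermal and appendage genes were lower in unwounded oral mucosa. Of 12 cornifying epidermis markers, 0 were higher and 10 lower (median -1.50, relative -0.90, percentile 0.03, TMM 1 and 9, -2.22 without part 3 of the oral section), with Krt1 1509-fold lower, Flg 2458-fold lower and Krt10 50.6-fold lower. Of 10 basal keratinocyte markers, 0 were higher and 9 lower (median -1.87, relative -1.27, percentile 0.01, -0.86 in spots with under 1% muscle markers), Krt15 being 8.13-fold lower and Krt14 6.93-fold lower. Hair follicle markers were lower for all 10 (median -1.09, relative -0.49, percentile 0), with Krt25 181-fold lower (log2 ratio -7.50, -12.81 to -5.01) and the stem cell receptor Lgr5 32.9-fold lower. Of 9 sebaceous gland markers, 1 was higher and 7 lower (median -2.38, relative -1.78, percentile 0.01), with Elovl3 817-fold lower and the desaturase Scd1 60.8-fold lower. Of 16 wound keratinocyte genes, 0 were higher and 13 lower (median -2.18, relative -1.58, percentile 0, TMM 3 and 13), with a log2 ratio of -5.32 (-5.51 to -5.14) for Krt17 and Sprr2d 43.6-fold lower. Proliferation genes were lower for all 12 (median -1.23, relative -0.63, percentile 0.58, TMM 0 and 7), with Mcm5 4.00-fold lower, and the median was -0.23 in spots with under 1% muscle markers.

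Immune and matrix genes were lower in unwounded oral mucosa than in the facial section, whose label may be wrong. Neutrophil markers (11 of 11 lower; median -2.62, relative -2.02, percentile 0), inflammatory cytokines (16 of 16; median -1.89, relative -1.29, percentile 0), macrophage markers (14 of 14; median -1.99, relative -1.39, percentile 0) and dendritic and Langerhans cell markers (10 of 10; median -1.30, relative -0.70, percentile 0.01) were lower without exception. S100a9 was 308-fold lower, Il1b 379.9-fold lower, the chemokine Ccl8 55.3-fold lower, the mannose receptor Mrc1 14.5-fold lower and H2-Aa 5.75-fold lower. Of 10 T and NK cell markers, 0 were higher and 9 lower (median -0.54, relative 0.06, percentile 1.26, TMM 0 and 7). Of 12 provisional matrix genes, 0 were higher and 11 lower (median -2.56, relative -1.96, percentile 0), with Postn 29.8-fold lower and Tnc 17.3-fold lower. Of 16 fibrillar collagen and matrix genes, 0 were higher and 14 lower (median -1.53, relative -0.92, percentile 0.02, TMM 1 and 10), with Col1a1 9.66-fold lower. Of 11 matrix metalloproteinases and inhibitors, 0 were higher and 10 lower (median -1.61, relative -1.01, percentile 0.01, TMM 1 and 8), with Mmp3 14.99-fold lower. Of 12 fibroblast markers, 3 were higher and 7 lower (median -1.18, relative -0.58, percentile 0.67, TMM 4 and 6), with Lum 9.76-fold lower.

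Endothelial, pericyte, muscle regeneration and erythrocyte lists were higher in unwounded oral mucosa relative to the all-gene median. Of 10 endothelial markers, 4 were higher and 0 lower (median 0.22, relative 0.82, percentile 99.9, TMM 10 and 0, -0.22 in spots with under 1% muscle markers), with Kdr, the VEGF receptor, 2.03-fold higher. Of 10 pericyte and smooth muscle markers, 7 were higher and 1 lower (median 0.92, relative 1.52, percentile 99.99, TMM 8 and 0, 0.23 without part 4 of the oral section), with Des and Tpm2, both also expressed in skeletal muscle, 18.7-fold higher and 15.8-fold higher. Of 6 muscle regeneration genes, 5 were higher and 0 lower (median 1.19, relative 1.79, percentile 100, 0.01 in spots with under 1% muscle markers), with perinatal myosin, Myh8, 121-fold higher. Erythrocyte genes were higher for all 5 (median 2.94, relative 3.54, percentile 99.8, 2.11 without part 4 of the oral section), with Hbb-bs 12.8-fold higher. Of 8 salivary gland markers, 6 were higher and 2 lower (median 0.52, relative 1.12, percentile 100, -1.09 without part 4 of the oral section and -2.17 in spots with under 1% muscle markers), with Lpo 614-fold lower (log2 ratio -9.26, -14.57 to -6.78). Schwann cell markers (1 higher and 1 lower of 6; median -0.03, relative 0.58, percentile 96.4, TMM 4 and 0) and interferon response genes (0 higher and 6 lower of 13; median -0.29, relative 0.31, percentile 85.8, TMM 1 and 2) turned from a negative median to 0.49 and 0.08 with TMM. Of 9 adipocyte markers, 2 were higher and 5 lower (median -0.62, relative -0.02, percentile 33.3), with Cfd 2.71-fold lower and Plin4 3.14-fold higher. Of 5 mast cell markers, 0 were higher and 4 lower (median -0.38, relative 0.22, percentile 62.5, TMM 1 and 0, 0.03 without part 1 of the facial section), with Mcpt4 2.13-fold lower. Of 14 hypoxia and glycolysis genes, 4 were higher and 4 lower (median 0.03, relative 0.63, percentile 99.4, TMM 7 and 4), with Aldoa 5.43-fold higher and Hif1a 4.06-fold lower. Of 13 efferocytosis genes, 0 were higher and 8 lower (median -0.60, relative 0.00, percentile 51.1, TMM 1 and 5), with Abca1 9.94-fold lower and Cd163 9.05-fold lower. Of 14 focal adhesion genes, 1 was higher and 8 lower (median -0.61, relative -0.01, percentile 69.0, TMM 4 and 5). Of 12 TGF beta pathway genes, 1 was higher and 8 lower (median -0.92, relative -0.32, percentile 2.40, TMM 3 and 4), with Tgfbi 3.92-fold lower and Tgfbr2 2.74-fold lower. Of 11 fibroblast lineage transcription factors, 1 was higher and 8 lower (median -0.43, relative 0.18, percentile 50.2, TMM 2 and 6), with Sox9 20.7-fold lower and Twist1 13.4-fold lower.

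The 10 highest genes over all in unwounded oral mucosa were Krt13, Krt4, Chil4 (5257-fold higher), Sprr3, myoglobin, Mb (270.1-fold higher), Cox8b, Myh2, Ckm, Cox7a1 and Cox6a2, and the 10 lowest were Krt1, Flg, Cstdc5, Stfa3, S100a9, S100a8, Saa3 (2576-fold lower, log2 ratio -11.33 between -13.61 and -9.78), Krt77 (at least 2423-fold lower), the fatty acid hydroxylase Fa2h (1078-fold lower) and Krt79. Of 359 measured list genes 79 were higher and 219 lower with CPM and 112 and 175 with TMM, or 26.5% and 39.0% higher among those counted.

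At day 4 skeletal muscle, muscle regeneration, neutrophil and cytokine genes were higher in oral mucosa than in facial skin. All 12 skeletal muscle markers were higher in oral mucosa (median 5.51, relative 5.87, percentile 100, 3.19 without part 3 of the oral section), Myh2 being 219.9-fold higher. Muscle regeneration genes were higher for all 9 (median 1.79, relative 2.15, percentile 100, 0.63 without part 2 of the oral section), with Myh8 103-fold higher, Myh3 10.8-fold higher and Myog 13.1-fold higher. Of 10 neutrophil markers, 7 were higher and 1 lower (median 1.52, relative 1.88, percentile 100), with S100a8 23.6-fold higher, S100a9 14.3-fold higher and Retnlg 19.1-fold higher. Of 14 inflammatory cytokines and chemokines, 10 were higher and 2 lower (median 0.89, relative 1.25, percentile 100), with Cxcl3 377-fold higher (log2 ratio 8.56, 7.00 to 10.84), Cxcl5 8.96-fold higher and Il1b 11.8-fold higher. Without part 2 of the oral section the neutrophil median was -0.04 and the cytokine median -0.19, and without part 3 the neutrophil median was 2.17. Of 14 macrophage and monocyte markers, 1 was higher and 1 lower (median -0.14, relative 0.22, percentile 91.1, TMM 4 and 1), with Mrc1 2.32-fold lower and Lyz2 1.90-fold higher, and their median was 0.18 with TMM, 0.32 without part 3 of the oral section, and 0.16 and 0.10 without part 1 or part 2 of the facial one.

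Epithelial and appendage differences at day 4 were large. Of 6 oral epithelium markers, 4 were higher and 1 lower (median 4.72, relative 5.08, percentile 99.99, 4.74 to 8.18 on leaving out 1 part), with Krt13 30405-fold higher and Krt4 14516-fold higher. Of 9 oral and craniofacial transcription factors, 7 were higher and 1 lower (median 0.98, relative 1.34, percentile 100, 2.24 and 2.25 without part 2 or part 3 of the oral section), with Pitx1 89.7-fold higher. Of 12 cornifying epidermis markers, 0 were higher and 11 lower (median -2.40, relative -2.04, percentile 0, -4.08 without part 2 of the oral section and -1.69 without part 3), with Krt1 3583-fold lower and Krt10 447-fold lower. Hair follicle markers were lower in oral mucosa for all 11 (median -1.28, relative -0.92, percentile 0), with Krt25 81.6-fold lower (log2 ratio -6.35, -11.66 to -3.86) and Dlx3 6.86-fold lower. Of 9 sebaceous gland markers, 0 were higher and 7 lower (median -2.49, relative -2.13, percentile 0), with Elovl3 at least 377-fold lower. Of 10 basal keratinocyte markers, 0 were higher and 8 lower (median -1.16, relative -0.80, percentile 0.08). Of 12 proliferation genes, 0 were higher and 11 lower (median -0.97, relative -0.61, percentile 0.07), with Top2a 3.05-fold lower. Of 15 wound keratinocyte genes, 5 were higher and 4 lower (median 0.19, relative 0.55, percentile 98.6, TMM 7 and 3), with Sprr1a 5.01-fold higher and Krt75 at least 38.3-fold lower. Their median was -0.76 and 0.81 without part 2 or part 3 of the oral section and -0.04 without part 3 of the facial one. Of 9 salivary gland markers, 7 were higher and 2 lower (median 3.22, relative 3.58, percentile 100, 3.85 without part 3 of the oral section and 1.47 without the gland region), with Muc5b at least 7845-fold higher.

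Matrix genes did not move together at day 4. Of 12 provisional matrix genes, 6 were higher and 4 lower (median 0.51, relative 0.87, percentile 99.8, TMM 6 and 2, -0.51 without part 2 of the oral section and 1.20 without part 3), with Spp1 6.78-fold higher and Thbs1 4.70-fold higher but Cthrc1 2.82-fold lower. Of 16 fibrillar collagen and matrix genes, 1 was higher and 7 lower (median -0.44, relative -0.08, percentile 28.3, TMM 2 and 4), with Col6a3 4.27-fold lower and Col6a1 3.55-fold lower. Of 12 fibroblast markers, 1 was higher and 6 lower (median -0.58, relative -0.22, percentile 10.9, TMM 2 and 2), with Col1a1 2.89-fold lower and the growth factor receptor Pdgfra 2.62-fold lower. Of 9 adipocyte markers, 0 were higher and 7 lower (median -1.27, relative -0.91, percentile 0), with Cfd 287-fold lower (log2 ratio -8.17, -11.21 to -6.31). Endothelial markers were higher in oral mucosa for 9 of 10 (median 0.58, relative 0.94, percentile 99.98). Of 10 pericyte and smooth muscle markers, 7 were higher and 1 lower (median 0.97, relative 1.33, percentile 100), with Des 28.7-fold higher and Tpm2 12.6-fold higher. Interferon response genes were lower for 9 of 13 (median -0.68, relative -0.32, percentile 0.14, TMM 0 and 6), with Bst2 2.38-fold lower and Irf7 2.65-fold lower. Of 12 TGF beta pathway genes, 3 were higher and 0 lower (median 0.11, relative 0.47, percentile 98.3, -0.32 without part 2 of the oral section), with Ltbp1 2.32-fold higher. Of 11 matrix metalloproteinases, 3 were higher and 4 lower (median -0.21, relative 0.15, percentile 78.1, TMM 4 and 3, 0.14 without part 1 of the facial section), with Adamts1 3.88-fold lower and Mmp9 4.67-fold higher.

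Oxidative phosphorylation and blood genes were higher in day 4 oral mucosa, and the remaining lists lay closer to the all-gene median. Oxidative phosphorylation genes were higher in oral mucosa for 12 of 13 (median 1.04, relative 1.40, percentile 99.6, 0.43 without part 3 of the oral section and 0.11 in spots with under 1% muscle markers), and erythrocyte genes for all 5 (median 3.68, relative 4.04, percentile 99.5, 1.60 without part 3). Of 7 mast cell markers, 0 were higher and 0 lower (median 0.16, relative 0.52, percentile 99.3, TMM 4 and 0, -0.96 without part 3 of the oral section and -0.02 without part 4 of the facial one). Of 14 focal adhesion genes, 5 were higher and 3 lower (median 0.05, relative 0.41, percentile 99.6, TMM 6 and 2), with Ankrd1 5.53-fold higher and Ccn2 3.88-fold higher. Of 10 dendritic and Langerhans cell markers, 0 were higher and 5 lower (median -0.48, relative -0.12, percentile 3.73, TMM 0 and 1), with Cd207 5.87-fold lower. Of 8 T and NK cell markers, 0 were higher and 3 lower (median -0.30, relative 0.06, percentile 6.83). Of 11 fibroblast lineage transcription factors, 1 was higher and 4 lower (median -0.37, relative -0.01, percentile 23.7), with Twist1 4.44-fold lower and Sox9 3.74-fold lower. Schwann cell markers (0 higher and 1 lower of 6; median -0.04, relative 0.32, percentile 82.5), efferocytosis genes (0 higher and 2 lower of 12; median -0.11, relative 0.25, percentile 90.6, TMM 1 and 0) and hypoxia and glycolysis genes (2 higher and 2 lower of 13; median -0.01, relative 0.35, percentile 94.6, TMM 6 and 1) had medians just below 0 that became 0.21, 0.14 and 0.30 with TMM. The 10 highest genes in the oral section were Krt13, Krt4, Sprr3, Muc5b, Mb, Myh2, the protease inhibitor Slpi (211-fold higher), Cox6a2, Dcpp1 and Cox8b, and the 10 lowest Krt1, Krt10, Krt77, Stfa3, Flg, Cstdc5, Krt79, Fa2h, Flg2 and the histidine ammonia-lyase Hal (517-fold lower, log2 ratio -9.02 between -11.29 and -7.47). Of 354 measured list genes 114 were higher and 118 lower with CPM and 139 and 90 with TMM, or 49.1% and 60.7% higher among those counted.

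Within each section, spots were grouped into regions by their expression and each region is named by its leading genes. In facial skin Gas6 was highest where muscle genes led. It stood at 498 CPM (458 to 540.0) in the Acta1-, Cryab- and Myh1-led region of the section labelled unwounded and at 719 CPM (659 to 783) in the Acta1-, Tnnc2- and Mylpf-led region at day 4, which also held the highest Axl of their sections, at 136 and 134 CPM. The unwounded region held 36.4% of that section's fibroblast-marker UMIs and 85.1% of its skeletal muscle UMIs. Regions led by Krt6a, Stfa1 and Stfa3 had 97.8 CPM of Gas6 in the section labelled unwounded and 87.2 at day 4. With a clustering resolution of 1, the highest Gas6 region of day 4 facial skin was led by Gpx3, C3 and Clec3b, at 992 CPM.

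In oral mucosa, regions differed less in Gas6. The Mir205hg-, Krt5- and Mki67-led region of the unwounded section was highest, at 144 CPM (124 to 166), and the Myh4-, Myom2- and Cfd-led region had 96.1 CPM and the highest Axl, 111 CPM. Clustering only spots with at least 1000 UMIs put both at their highest in a Cfd-, Cytl1- and Acta2-led region, at 209 CPM of Gas6 and 295 of Axl. In the day 4 oral section Gas6 was highest in the Postn-, Myh4- and Cthrc1-led region, at 131 CPM (104 to 162). Axl was highest in the Ppbp-, Cxcl3- and Krt17-led region, at 104 CPM (79.2 to 133), where Gas6 was lowest, at 32.3 CPM (19.4 to 50.4). That region held 75.7% of the section's neutrophil-marker and 74.6% of its cytokine UMIs in 19.6% of all its UMIs. In the section labelled unwounded facial skin, S100a8 and S100a9 gave 36155 and 32793 of 78451 neutrophil-marker UMIs. The Areg-, Stfa3- and Krt6a-led region held 40.1% of the 78451 and the Cxcl2-, Il1b- and Cd14-led region 18.1%, with 28.6% of cytokine UMIs. At day 4 the Cxcl5-, Spp1- and S100a9-led facial region held 37.3% of that list's UMIs, with Gas6 at 249 CPM (210.3 to 294).

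**Figure D3:**
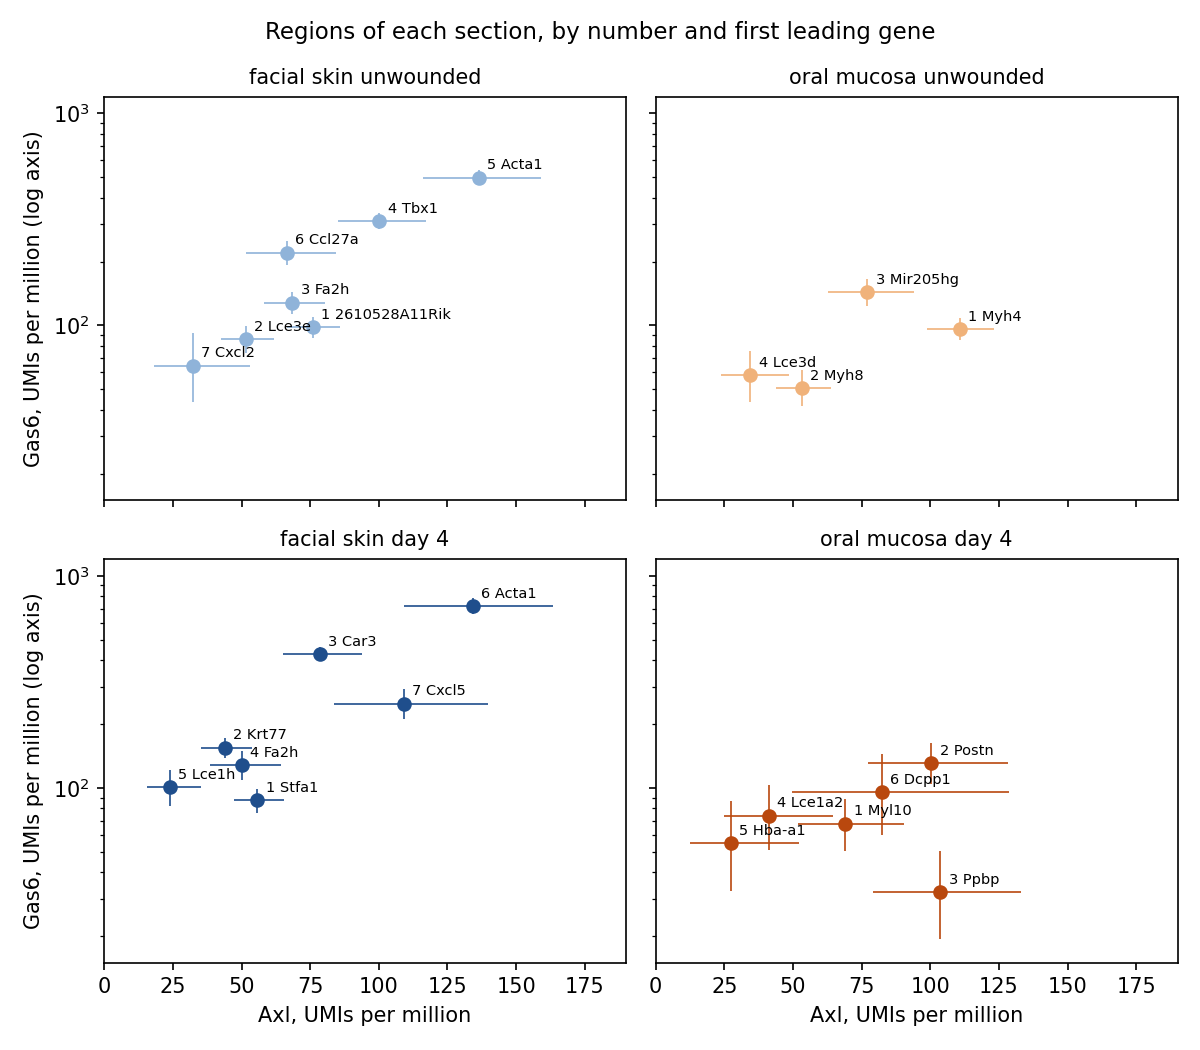
Gas6 (vertical axis, CPM, log scale) against Axl (horizontal axis, CPM) in the regions holding at least 1% of a section's UMIs, coloured by section, with bars for exact 95% Poisson intervals of counting error only. Facial regions reach 498 and 719 CPM of Gas6 where muscle genes lead, and in the Ppbp-, Cxcl3- and Krt17-led region of day 4 oral mucosa Gas6 is at 32.3 CPM with Axl at 104.

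Across spots of facial skin Gas6 went with fibroblast and macrophage markers and against cornifying markers. Spearman's rho with the fibroblast-marker share of a spot was 0.57 in the section labelled unwounded and 0.35 at day 4, at percentiles 96.5 and 93 among 200 genes of similar level. With macrophage markers it was 0.54 and 0.39 (percentiles 96 and 96.5), and with adipocyte markers 0.44 and 0.40 (95 and 98.5). Dendritic, Schwann and T and NK cell markers had 0.50, 0.47 and 0.45 in the section labelled unwounded, each at percentile 98, and 0.24, 0.24 and 0.21 at day 4. With cornifying markers it was -0.48 and -0.33 (7 and 7), and with basal keratinocyte markers -0.34 and -0.30 (5 and 4.5), the -0.34 running from -0.48 to 0.08 within single parts. With neutrophil markers it was -0.44 and -0.06 (0 and 2), but ran from -0.35 to 0.17 and from -0.15 to 0.04 within single parts. Facial Axl had rho 0.26 and 0.01 with fibroblast markers (88.5 and 87). In unwounded oral mucosa rho with fibroblast markers was 0.41 for Gas6 (94.5) and 0.42 for Axl (99), and over spots with at least 1000 UMIs the Gas6 value was 0.229. In day 4 oral mucosa Gas6 had rho 0.03 with fibroblast markers (80.5) and 0.29 with mast cell markers (99.5). Spots are not independent, and these values describe single sections.

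Gas6 had at least 1 UMI in 76.6% of spots in the section labelled unwounded facial skin, 70.2% in day 4 facial skin, 25.4% in unwounded oral mucosa and 32.3% in day 4 oral mucosa, and Axl in 64.2%, 36.0%, 23.9% and 34.0%. After thinning each spot to 1000 UMIs, which left out 18, 45, 765 and 65 spots, the Gas6 shares were 15.01%, 24.9%, 10.1% and 8.77% and the Axl shares 7.04%, 8.03%, 9.56% and 6.58%. In that order, spots held both genes 1.03, 1.05, 1.07 and 1.06 times as often as their shares at matched depth gave. Expected shares lay in the 95% intervals but come from the same spots, taken as independent, so excess is untested.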

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

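The tests of epithelium below were written down before their result was seen, and all other tests in this part were chosen after the result they address. Of the results compared between the tissues, 5 went opposite ways by at least 1.5-fold in each tissue between day 4 and unwounded sections, and each of these differences was not tested, since a group held 1 section. Oral minus facial, the log2 wound ratio of Pros1, which encodes the TAM ligand protein S, differed by 1.87 (1.28 in oral mucosa and -0.60 in facial skin, which fell below 1.5-fold with TMM and, at -0.51, with 10 CPM added). List medians differed by 3.34 for neutrophil markers (1.83 and -1.51), by 2.97 for inflammatory cytokines and chemokines (1.47 and -1.50), by 1.96 for wound keratinocyte genes (1.10 and -0.86) and by -1.95 for adipocyte markers (-1.11 and 0.84). The last 2 fell below 1.5-fold without 1 part, at 0.18 for oral wound keratinocyte and -0.24 and 0.42 for oral and facial adipocyte genes, and averaged over spots at 0.52 and -0.53 in oral mucosa.

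The first pattern weighed is that neutrophil genes such as S100a8 and cytokine genes such as Cxcl2 were higher in the facial section labelled unwounded than in the one labelled day 4. A swap of the 2 facial labels stays open, since the lists of wound genes parted, with medians of 0.57 (0.30 to 0.97) for muscle regeneration, -0.86 (-1.14 to -0.57) for wound keratinocyte, -0.50 (-0.83 to -0.03) for metalloproteinase and -0.48 (-1.29 to 0.72) for provisional matrix genes. Without 1 region of the section labelled unwounded, the neutrophil median with the highest upper bound was -1.10 (-3.45 to -0.33). For cytokine genes it was -1.12 (-1.49 to -0.70). These values argue against 1 inflamed region for cytokine genes but leave it open for neutrophil genes, whose interval reaches within 1.5-fold of 0. A patch across regions was not tested. A difference between the 2 animals, or a single wrong label, could not be told apart from an effect of wounding: Xist stood at 91.5 CPM in the day 4 section and at 1 UMI in the other. The biological explanation, facial skin past its neutrophil phase at day 4, would need an unwounded section without this signal and remains untested.

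The second pattern is that there were fewer Gas6 UMIs per Axl UMI in oral mucosa than in facial skin. Skeletal muscle fills much of the oral sections, and in spots with under 1% muscle markers the log2 difference, oral minus facial, was -0.49 (-0.84 to -0.15) unwounded and -1.69 (-2.08 to -1.30) at day 4, against -1.08 and -1.80 over all spots. Muscle may therefore account for part of the unwounded difference. Whether it accounts for all of it is open, because skeletal muscle genes remained higher in oral mucosa within these unwounded spots. In spots with under 1% epithelial markers it was -2.35 (-2.92 to -1.78) and -2.59 (-3.09 to -2.09), which argues against epithelium alone. Other cell types were not matched, and the unwounded facial side rests on 23 of 671 spots with 280 Gas6 and 65 Axl UMIs. That the tissues set the ratio is open, since each was seen in 2 sections and animal differences were not tested.

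The third pattern is that neutrophil and provisional matrix genes such as Postn were higher in the oral section labelled day 4. Blood would carry neutrophil markers. The Hba-a1-led region, with 71.9% of erythrocyte-gene and 10.9% of all UMIs, held 0.224% of the 11589 neutrophil-marker UMIs. S100a9 (5696) and S100a8 gave most of these, so others weigh little. No single part accounts for the provisional matrix genes, whose lowest median without a part was 1.46. The values fit an inflamed wound with early matrix, but sex and animal differ with wounding and were not tested.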

How the results depend on the processing

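Of the alternatives here, leaving out the inflamed facial region or the oral gland region, the mean over spots with at least 1000 UMIs, the fibroblast reference without Gsn, and regions and joint shares from spots with at least 1000 UMIs were chosen after seeing the data, and the rest before. The 140 list medians gave 2380 alternative values, of which 2238 kept their sign. Of all 2380, 2124 stayed within the main interval, 242 moved outside it and 14 reversed, changing sign where that interval held a single sign. No cause of a change below was tested. Pairing was not possible, as the labels give no animal shared between sections. All 70 medians computed without the inflamed facial region kept their sign and stayed within the interval, and this region held 18.1% of the neutrophil-marker UMIs. With spots of at least 1000 UMIs 139 of 140 signs were kept, but these spots hold 7225607 of the 7285023 UMIs of the unwounded oral section, so sums could change little.

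With TMM scaling 129 of 140 medians kept their sign. In day 4 against unwounded oral mucosa Gas6 moved to -0.53, Axl to -0.41 and the TAM receptor list to -0.34. In unwounded oral mucosa against facial skin Gas6 moved to -0.27, Axl to 0.80, macrophage markers to -1.35 and collagen genes to -0.85, and interferon response genes reversed from -0.29 to 0.0826. Between the day 4 tissues Gas6 was -1.16 and Axl 0.64. With a total free of mitochondrial and abundant genes 130 signs were kept, with Gas6 at -0.52 and Axl at 0.56 between the unwounded tissues and -1.26 and 0.53 at day 4.

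Counted per fibroblast-marker UMI, Gas6 and Axl had log2 ratios of -0.17 (a reversal) and -0.78 in day 4 against unwounded facial skin, -0.81 and -0.69 in oral mucosa, -0.18 and 0.89 between the unwounded tissues, and -0.82 and 0.98 at day 4. Without Gsn in the reference they were -0.20 (a reversal) and -0.80, -1.72 and -1.60, 0.82 (a reversal) and 1.90, and -0.69 and 1.10.

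Averaging over spots kept 122 of 140 signs. Between the facial sections it gave 0.96 for Gas6, 1.15 for fibroblast markers, -1.19 for wound keratinocyte genes and 1.06 for collagen genes, and it reversed Axl to 0.0839, macrophage markers to 0.18, Schwann cell markers to 0.0487 and efferocytosis genes to 0.0468. Axl was -0.75 and wound keratinocyte genes 0.52 in the oral wound comparison, Axl 0.93 between the unwounded tissues and Gas6 -2.04 between the day 4 tissues. The mean over spots with at least 1000 UMIs gave 0.91 for Gas6 and -0.0198 for Axl between the facial sections, -0.86 and 0.42 between the unwounded tissues, and -2.05 for Gas6 at day 4.

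With a pseudocount of 1 CPM 139 signs were kept and medians grew. Cytokine genes were at -2.89 and muscle regeneration genes at 1.64 in the facial wound comparison. In the oral one macrophage markers were at 2.28, neutrophil markers at 4.44, cytokine genes at 3.32 and muscle regeneration genes at 2.32. Between the unwounded tissues macrophage markers were at -2.52, wound keratinocyte genes at -3.36, provisional matrix genes at -3.31 and cytokine genes at -3.95, and muscle regeneration genes were at 3.02 at day 4. Minimums of 100 UMIs or none kept 136 signs each.

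In spots with under 1% skeletal muscle markers 123 signs were kept. Axl was 0.19 and cytokine genes 2.17 in the oral wound comparison, where oxidative phosphorylation genes reversed to 0.0908. Between the unwounded tissues Gas6 was -0.72, Axl -0.22 and muscle regeneration genes 0.0122, and oxidative phosphorylation genes reversed to -0.0935. Macrophage markers were 0.27 and wound keratinocyte genes 0.85 at day 4. Without the oral gland region 65 of 70 signs were kept.

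Leaving out 1 part of a section kept 1049 of 1120 signs. Of these, 210 medians left out 1 of 3 parts that hold under 5% of their section's UMIs and so could change little, and 209 of them kept their sign, against 840 of 910 for the larger parts, a split chosen after seeing the data. In the facial wound comparison Gas6 ran from -0.0191 (a reversal, without part 2 of the section labelled unwounded) to 0.61, fibroblast markers from 0.0870 to 0.68, macrophage markers from -0.68 to -0.13 and collagen genes from 0.00127 to 0.75. In the oral one Axl ran from -0.40 to 0.15, macrophage markers from 0.96 to 1.87, wound keratinocyte genes from 0.18 to 1.69, collagen genes from 1.06 to 2.02, provisional matrix genes from 1.46 to 3.27, cytokine genes from 0.63 to 2.03 and muscle regeneration genes from 0.31 to 1.83. There mast cell markers (-0.00451 to 1.49), skeletal muscle markers (-2.79 to 0.32), focal adhesion genes (-0.0793 to 0.91) and oxidative phosphorylation genes (-1.08 to 0.14) reversed. Between the unwounded tissues Gas6 ran from -1.34 to -0.72 and macrophage markers from -2.29 to -1.67. At day 4 Axl (-0.0478 to 0.50), neutrophil markers (-0.0358 to 2.17) and cytokine genes (-0.19 to 1.44) reversed without part 2 of the oral section. Fibroblast markers ran from -0.94 to -0.21, macrophage markers from -0.56 to 0.32, wound keratinocyte genes from -0.76 to 0.81, collagen genes from -0.87 to -0.0483, provisional matrix genes from -0.51 to 1.20 and muscle regeneration genes from 0.63 to 2.30.

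At resolution 1 the highest Gas6 region of day 4 facial skin, led by Gpx3 and C3, was at 991.5 CPM. Clustering spots with at least 1000 UMIs put the highest Gas6 region at 208.5 CPM in unwounded oral mucosa, 914.1 in day 4 facial skin and 168.2 in day 4 oral mucosa, and the highest Axl region at 295.1 and 136.4 CPM in the 2 oral sections. In the unwounded oral section, where 765 spots held under 1000 UMIs, leaving these out brought rho to 0.229 for Gas6 with fibroblast markers, 0.188 for Gas6 with macrophage markers and 0.256 for Axl with macrophage markers. It reversed rho of Gas6 with neutrophil (-0.00525), pericyte (-0.132), skeletal muscle (-0.229), oral epithelium (0.0679) and erythrocyte (-0.0808) genes and of Axl with skeletal muscle markers (-0.0854).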

Other observations

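No test was run for this part. Erythrocyte genes took 0.0405% of UMIs in the section labelled unwounded facial skin, 0.139% in day 4 facial skin, 0.421% in unwounded oral mucosa and 1.89% in day 4 oral mucosa. Xist had 1, 909, 0 and 84 UMIs in that order, and Ddx3y 587, 0, 280 and 0.

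The correlation across genes of the facial and oral wound ratios was -0.0781 by Pearson and 0.00679 by Spearman over the 8285 genes with at least 500 UMIs, of which 46.7% had the same sign in both tissues.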
